A study of Saccharomyces cerevisiae with 55 samples.

How the data were processed

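The samples were 55 two-colour arrays of Saccharomyces cerevisiae RNA, each hybridized with a mutant or treated RNA and a reference RNA. The deposited table holds 1 column of log2 ratios per array, read as log2 because they are signed, centre near 0 and reach an absolute value of 15.58, beyond a scanner's range in a larger base. The base is not given in the sources used here, so every log2 value rests on that reading. Nor is it given how the authors normalized, scaled or centred the ratios, and intensities were not used. KCl was 0.375 M, H2O2 0.4 mM, heat 42 °C and rapamycin 200 nM, each for 20 min.

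Of 6317 entries 61 control spots were left out, which left 6256 probes. Of these 4075 carried 1 gene symbol, none carried several and 2181 carried none. Symbols were matched to the yeast reference annotation, which was used for names only: 3942 matched directly, 129 were updated from a synonym and 4 were kept without a match. Probes of the 7 symbols with more than 1 probe were averaged, giving 6249 genes or probes, of which 4413 had a value on every assigned array. In 3 columns, given with more decimals than the others, exact zeros were set to missing (407 values). Arrays held 5220 to 6213 values. Array medians ran from -0.09 to 0.05 in the columns with 2 decimals and reached 0.38 on the array of wild type with rapamycin, and no centring was applied.

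Arrays were grouped by their labels into 27 comparisons, and 1 array was left out of every comparison because its sample sources name kcs1vip1 in KCl in both channels, while its title sets kcs1vip1 in KCl against kcs1vip1. The 3 dye-swapped arrays were used with the sign as deposited. A group-means model was fitted with limma 3.58.1 in R 4.3.3 to the log2 ratios, with empirical Bayes moderation (27 residual degrees of freedom for a gene on every array, 4.63 prior degrees of freedom, prior SD 0.369, median residual SD 0.398). A comparison was tested for genes with at least 2 values on each side, p-values were adjusted by Benjamini-Hochberg within each comparison, and the threshold was an adjusted p of 0.05. Differences between groups, such as KCl minus log within a mutant or kcs1vip1 minus vip1 in KCl, were contrasts of this model. Comparisons with 1 array were not tested. There, each list median was placed among those of 10000 random lists of the same size.

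The 33 gene lists were common stress-induced, ribosomal protein, ribosome biogenesis, RNA polymerase I and III, osmotic, heat shock, oxidative, phosphate, arginine, Gcn4, inositol and phospholipid, meiotic, nitrogen, retrograde, iron, a-cell specific, alpha-cell specific, haploid-specific, pheromone response, oxidative phosphorylation, mitochondrially encoded, mitochondrial ribosome, glycolysis, histone, G1/S, G2/M, proteasome, endoplasmic reticulum stress, seripauperin, altered genes, marker genes, inositol pyrophosphate pathway, and Rpd3 and Set3 complex genes. Lists were tested with fry from limma on the genes with a value on every array, adjusted over lists within a comparison, and again with camera with an estimated correlation between genes. Members were counted with p adjusted over all genes and again over the list alone.

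The genes named are the altered genes and markers, then the 10 highest and 10 lowest genes with a symbol that passed with all arrays in the same direction for wild type KCl, kcs1vip1 log, kcs1vip1 KCl minus log and rapamycin in KCl, 3 and 3 for other tested comparisons, 5 and 5 for single arrays, and up to 4 of the largest members of a discussed list. Whether probes of near-identical genes, such as PHO11 and PHO12, measure 1 gene each was not tested. A mutant's KCl slope was that of its KCl minus log difference on wild type ratios, through the origin. It was taken over the 2138 genes that passed and changed at least 2-fold in wild type. The strain signature was the same slope, on the kcs1vip1 log ratios, over 18 genes that the stresses did not move.

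The model was tested on simulated data with the real design. It recovered 75.8% of genes with a true log2 change of 1 in wild type KCl, 58.0% in kcs1vip1 KCl minus log and 32.0% in kcs1 KCl minus log, and 100.0%, 99.0% and 82.0% of those with a change of 2, with 10, 22 and 3 unchanged genes called. A 40-gene list shifted by 0.5 had a fry adjusted p of 1.27e-14. None of 20 random lists was called, which does not test lists of correlated genes.

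Alternatives were array median centring, scaling arrays to the same spread, only genes on every array, slide as a random block (correlation 0.301) or as a fixed block, a dye term, robust moderation, a coefficient per RNA source, fixed lists in place of the genes that passed for slopes, genes past the threshold in either comparison for similarities, camera, and leaving out each array in turn. Added after the data were seen were turning the sign of the dye-swapped Vip1D487A arrays, leaving out 5 doubted arrays, and keeping exact zeros. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.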

Results

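The 55 yeast arrays gave log2 ratios for 5220 to 6213 genes or probes, and 54 were assigned to 27 comparisons with a reference RNA. Of these comparisons 7 had 3 arrays, 13 had 2 and 7 had 1, and the number of arrays limits the precision. The strains lacked or altered genes of inositol pyrophosphate synthesis (KCS1, VIP1, IPK1, ARG82) or of histone deacetylase complexes (RPD3, SNT1), and cells were in log growth, in KCl, in H2O2, in heat or with rapamycin. Values are mean log2 ratios ± SD over arrays, with n = 3 or 2 as given at the head of each comparison. A gene rose or fell where its limma adjusted p was below 0.05. The labels do not say that the arrays of a group come from separate cultures, so every p-value measures only the spread between arrays. Gene lists were fixed before the data were examined. For lists, fry tests whether a set moves on balance in 1 direction and compares it with no other genes, and a median given after a list is that of all its measured members. Counts adjusted over the list alone are given where they differ from those adjusted over all genes.

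The altered genes were low or missing on most arrays of their mutants. KCS1, which encodes an inositol hexakisphosphate kinase, fell by 7.12 ± 0.06 (2 values on 3 arrays) in kcs1vip1 in log growth, and its only value on the kcs1vip1 KCl arrays was -7.41. VIP1, the second kinase of this pathway, had 1 value of -9.33 in kcs1vip1 in log growth and none in KCl, and values of -4.90 in vip1 in log growth and -5.44 in KCl. ARG82, the inositol polyphosphate multikinase, had values of -4.17 and -5.78 on 1 array each of arg82 in log growth and KCl. SNT1, of the Set3 complex, had 1 value of -7.77 in snt1 in KCl. IPK1, the inositol pentakisphosphate kinase, had no value on any ipk1 array, and RPD3 none on either rpd3 array. RPD3 was 0.18 ± 0.23 in log growth and 0.21 ± 0.13 in KCl in Rpd3ibs (n = 2 each) and did not pass in either. On the 2 arrays labelled kcs1 in log growth KCS1 was -5.29 and -0.30, and the second of these carried IPK1 at -2.87 and LEU2 at -2.50. No array labelled kcs1vip1 over wild type in H2O2 had a value for KCS1 or VIP1, and the array labelled kcs1vip1 over wild type in heat had VIP1 at -0.01.

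KCl for 20 min raised the glycerol transporter STL1 by 12.62 ± 0.66, the catalase CTT1 by 11.36 ± 0.72 and the aldehyde dehydrogenase ALD3 by 11.36 ± 1.10 in wild type cells (n = 3). HXT5 (11.40 ± 1.12), PHM7 (10.88 ± 0.37), DDR2 (10.63 ± 1.04), HSP12 (10.08 ± 0.78), SPI1 (9.45 ± 0.58), GPD1 (8.94 ± 0.54), which encodes the glycerol-producing dehydrogenase, and MSC1 (8.92 ± 0.73) also rose. The largest falls of named genes were in the nucleolar protein gene NSR1 (-6.87 ± 0.10), in NOC2 (-6.18 ± 0.77), RRP12 (-6.13 ± 0.20), DHR2 (-5.80 ± 0.13, 2 values), KRE33 (-5.79 ± 0.63), RRP5 (-5.78 ± 0.23), RLP24 (-5.77 ± 0.20) and NOG1 (-5.66 ± 0.58), all of ribosome assembly, and in the phosphate transporter PHO84 (-6.12 ± 1.03) and the CTP synthase URA7 (-5.98 ± 1.36). All 62 measured common stress-induced genes rose (median 4.42, fry adjusted p = 3.18e-19, adjusted p = 0.0331 with an estimated correlation), and so did all 16 osmotic stress genes. Their median was 6.87 (fry adjusted p = 1.75e-20). All 111 ribosome biogenesis genes fell (median -4.27, fry adjusted p = 1.02e-18), as did all 23 subunit genes of RNA polymerases I and III, RPA43 at -5.07 ± 0.88 and RPA49 at -4.80 ± 0.23. Their median was -2.82 (fry adjusted p = 1.33e-18). Of 135 ribosomal protein genes 43 fell, 1 rose and 91 did not pass (40 and 1 adjusted over the list alone), among them RPL7B (-4.94 ± 0.09) and RPL22B (-3.98 ± 0.34). Their median was -0.50 (fry adjusted p = 7.23e-06, adjusted p = 0.585 with an estimated correlation). In all, limma called 3571 of 5863 genes, 1738 up and 1833 down, of which 1047 and 1091 changed at least 2-fold. After each array was scaled to the same spread the count was 2169.

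In wild type cells in KCl 16 of 21 G1/S genes fell, 1 rose and 4 did not pass, with RNR1 at -2.58 ± 0.51 and POL1 at -2.51 ± 0.52. Their median was -1.34 (fry adjusted p = 2.54e-12, adjusted p = 0.242 with an estimated correlation). Of 19 G2/M genes 14 fell, 2 rose and 3 did not pass, with CLB2, the mitotic cyclin, at -2.65 ± 0.33. Their median was -1.61 (fry adjusted p = 3.1e-14, adjusted p = 0.198 with an estimated correlation). Of 24 heat shock genes 13 rose, 2 fell and 9 did not pass, with HSP26 at 5.78 ± 1.59 and HSP42 at 5.44 ± 0.19. Their median was 0.75 (fry adjusted p = 6.87e-07, adjusted p = 0.543 with an estimated correlation). Of 21 oxidative stress genes 11 rose, 1 fell and 9 did not pass (TSA2 2.86 ± 0.12). Their median was 0.57 (fry adjusted p = 3.03e-05, adjusted p = 0.543 with an estimated correlation). Proteasome genes rose in 20 of 32 cases with 12 not passing (21 adjusted over the list alone), PRE4 by 1.18 ± 0.24. Their median was 0.62 (fry adjusted p = 1.87e-06, adjusted p = 0.543 with an estimated correlation). Glycolysis genes rose in 10 of 16 cases with 6 not passing, TDH1 by 4.36 ± 0.45. Their median was 0.98 (fry adjusted p = 0.000153, adjusted p = 0.585 with an estimated correlation). Oxidative phosphorylation genes included 15 that rose, 2 that fell and 17 that did not pass of 34, SDH4 rising by 2.64 ± 0.81. Their median was 0.52 (fry adjusted p = 0.00119, adjusted p = 0.611 with an estimated correlation). Retrograde targets, which answer mitochondrial dysfunction, rose in 6 of 9 cases with 3 not passing, CIT1 by 3.38 ± 0.37 and CIT2 by 3.28 ± 0.38 (median 0.65, fry adjusted p = 3.58e-11, adjusted p = 0.307 with an estimated correlation).

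Nutrient genes went both ways in KCl. Phosphate starvation genes fell in 14 of 17 cases, with 1 rising and 2 not passing, PHM6 at -5.44 ± 0.31 and PHO12 at -4.34 ± 0.41. Their median was -2.23 (fry adjusted p = 1.01e-06, adjusted p = 0.543 with an estimated correlation). Targets of Gcn4, the activator of amino acid synthesis, included 22 that fell, 1 that rose and 13 that did not pass of 36, MET6 at -3.70 ± 0.87. Their median was -0.75 (fry adjusted p = 3.53e-07, adjusted p = 0.543 with an estimated correlation). Of 10 arginine genes 6 fell, 2 rose and 2 did not pass, CPA1 at -2.97 ± 0.35 and CAR1 rising by 2.66 ± 0.33. Their median was -0.72 (fry adjusted p = 0.00352, adjusted p = 0.801 with an estimated correlation). Nitrogen catabolite genes were split, 11 rising, 7 falling and 8 not passing of 26, PUT4 at 6.36 ± 0.25 and MEP2 at -3.71 ± 0.58. Their median was 0.17 (fry adjusted p = 2.1e-06, adjusted p = 0.599 with an estimated correlation). Iron genes rose in 15 of 24 cases, with 1 falling and 8 not passing (16 and 1 adjusted over the list alone), HMX1 by 5.14 ± 0.29 and TIS11 by 4.40 ± 0.66. Their median was 1.02 (fry adjusted p = 7.31e-09, adjusted p = 0.504 with an estimated correlation). Mitochondrial ribosome genes included 21 that fell, 3 that rose and 33 that did not pass of 57 (15 and 1 adjusted over the list alone), MRPL37 at -1.56 ± 0.44. Their median was -0.37 (fry adjusted p = 0.0206, adjusted p = 0.801 with an estimated correlation). This call was lost without wild type KCl replicate 1 (fry adjusted p = 0.134) or 2 (0.0638).

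Of 7 a-cell specific genes 4 fell, 1 rose and 2 did not pass (5 and 1 adjusted over the list alone), in KCl, with MFA2 at -3.18 ± 0.34. Their median was -0.66 (fry adjusted p = 0.00015, adjusted p = 0.677 with an estimated correlation). Of 11 haploid-specific genes 6 fell, 3 rose and 2 did not pass, FAR1 at -3.91 ± 0.48 and HO at -4.54 ± 1.52. Their median was -0.56 (fry adjusted p = 7.52e-12, adjusted p = 0.494 with an estimated correlation). The meiotic list had 10 genes that rose, 3 that fell and 9 that did not pass of 22 (11 and 3 adjusted over the list alone), SIP4 rising by 3.49 ± 0.40. Its median was 0.56 and its mean 0.59, while fry, which used only the 5 genes on every array, gave the direction down with adjusted p = 0.014 (adjusted p = 0.801 with an estimated correlation, and fry adjusted p = 0.153 without wild type KCl replicate 3). Pheromone response genes were not called (6 of 15 rose, 1 fell and 8 did not pass, 5 and 1 adjusted over the list alone, median 0.12, fry adjusted p = 0.0677), though PRM8 rose by 4.25 ± 0.48.

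Other lists were not called in wild type KCl. Inositol and phospholipid genes had 5 rising, 2 falling and 6 not passing of 13, CHO1 at 1.67 ± 0.82 (median -0.06, mean 0.19, fry direction up with adjusted p = 0.145). Endoplasmic reticulum stress genes had 4 rising, 3 falling and 6 not passing of 13, MPD1 at 1.62 ± 0.45 (median -0.19, mean 0.18, fry direction up with adjusted p = 0.151). Of 10 histone genes 4 fell and 6 did not pass (3 adjusted over the list alone), HTB2 at -0.90 ± 0.34. Their median was -0.55 (fry adjusted p = 0.145). Among 14 seripauperin genes 5 rose, 7 fell and 2 did not pass. Their median was -0.50 (fry adjusted p = 0.36). Of 20 genes of the Rpd3 and Set3 complexes 5 rose, 3 fell and 12 did not pass (3 and 3 adjusted over the list alone), PHO23 rising by 1.69 ± 0.55 and ASH1 at -1.41 ± 0.30. Their median was 0.22 (fry adjusted p = 0.525). None of 4 alpha-cell specific genes passed (median 0.00), and of 6 mitochondrially encoded genes 1 rose, VAR1 by 1.02 ± 0.91, and 5 did not pass (none adjusted over the list alone, median 0.07). These lists were too small on every array for a test, as were the 6 altered genes (1 rose, 2 fell, 3 did not pass, 1 and 1 adjusted over the list alone) and the 8 inositol pyrophosphate pathway genes (1 rose, 3 fell, 4 did not pass, 1 and 1 adjusted over the list alone, median -0.37). In the pathway INM1 fell by 1.45 ± 0.65 and ARG82 rose by 0.76 ± 0.24. The 6 marker genes had 2 rising, 2 falling and 2 not passing (median -0.12, fry adjusted p = 0.883).

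H2O2 for 20 min in wild type cells (n = 2) raised HSP30, a heat shock membrane protein gene, by 7.11 ± 2.06, SOR1 by 6.93 ± 1.35 and FIT2, of iron uptake, by 6.46 ± 1.42. URA7 (-3.90 ± 0.01) fell, and so did AI4 (-3.57 ± 0.16) and AI5_BETA (-3.48 ± 0.34), which lie in introns of the mitochondrial COX1. The median of the mitochondrial chromosome, less that of the array, was -1.56 and -2.27 on these arrays. Oxidative stress genes rose in 15 of 21 cases, with 1 falling and 5 not passing, GPX2 by 4.84 ± 0.90, AHP1 by 4.01 ± 0.04 and TRX2 by 3.60 ± 0.52. Their median was 1.13 (fry adjusted p = 1.17e-11, adjusted p = 0.0325 with an estimated correlation). Of 23 iron genes 19 rose and 4 did not pass. Their median was 2.17 (fry adjusted p = 1.17e-11). Of 62 common stress-induced genes 56 rose, 1 fell and 5 did not pass (57 and 1 adjusted over the list alone, median 2.14, fry adjusted p = 1.07e-08, adjusted p = 0.0894 with an estimated correlation), with DDR2 at 5.66 ± 0.34 and HSP42 at 4.43 ± 0.54. Ribosome biogenesis genes fell in 105 of 111 cases with 6 not passing (109 adjusted over the list alone), PWP2 at -3.46 ± 0.43 and UTP20 at -3.45 ± 0.01. Their median was -1.98 (fry adjusted p = 7.92e-09, adjusted p = 0.0618 with an estimated correlation). G2/M genes fell in 15 of 19 cases with 4 not passing (median -1.46, fry adjusted p = 1.17e-11), and glycolysis genes rose in 11 of 16 cases with 5 not passing, ENO1 by 3.09 ± 0.66. Their median was 2.50 (fry adjusted p = 0.000104, adjusted p = 0.335 with an estimated correlation). limma called 2490 of 5735 genes, 1261 up and 1229 down. The count was 1062 without wild type H2O2 replicate 1 and 1510 after scaling to the same spread.

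Log-growth kcs1vip1 cells (n = 3) carried HSP12 higher by 6.11 ± 0.83, FIT2 by 5.62 ± 0.60, PIR3 by 4.75 ± 1.36, DDR2 by 4.56 ± 0.35 and HSP30 by 4.55 ± 0.78. BAG7 (4.48 ± 0.16), PDH1 (4.04 ± 0.28), XBP1 (3.88 ± 0.22, 2 values), TIS11 (3.77 ± 0.51) and SIT1 (3.56 ± 0.49) also rose. After KCS1 itself the largest falls of named genes with all arrays in the same direction were in OAC1 (-5.56 ± 0.22), a mitochondrial isopropylmalate carrier, LEU1 (-5.53 ± 0.66) and LEU2 (-4.18 ± 0.20), of leucine synthesis, in BAR1 (-4.55 ± 0.58), which degrades alpha-factor, RPI1 (-4.25 ± 0.47), ARG3 (-4.20 ± 0.79), ARG1 (-4.10 ± 1.01), GDH1 (-4.01 ± 0.37) and SST2 (-3.97 ± 0.45). Common stress-induced genes rose in 47 of 62 cases, with 1 falling and 14 not passing (49 and 1 adjusted over the list alone, median 1.25, fry adjusted p = 8.74e-07, adjusted p = 0.15 with an estimated correlation), while the ribosome biogenesis median was -0.34 and was not called. Iron genes rose in 16 of 23 cases, with 1 falling and 6 not passing (18 and 2 adjusted over the list alone), FIT3 by 3.55 ± 0.70. Their median was 1.41 (fry adjusted p = 1.1e-07, adjusted p = 0.15 with an estimated correlation). Retrograde genes rose in 6 of 9 cases, with 1 falling and 2 not passing, CIT2 by 2.39 ± 0.58, IDH1 by 2.37 ± 0.14 and IDH2 by 2.16 ± 0.49. Their median was 1.10 (fry adjusted p = 4.37e-09, adjusted p = 0.15 with an estimated correlation). Gcn4 targets fell in 29 of 36 cases, with 2 rising and 5 not passing (median -1.05, fry adjusted p = 8.43e-09, adjusted p = 0.15 with an estimated correlation), and arginine genes in 7 of 10, with 2 rising and 1 not passing (8 and 2 adjusted over the list alone). Their median was -1.56 (fry adjusted p = 3.19e-08, adjusted p = 0.182 with an estimated correlation). Of 7 a-cell specific genes 6 fell and 1 did not pass, STE2 at -3.16 ± 0.43 and MFA1 at -2.46 ± 1.27. Their median was -2.33 (fry adjusted p = 5.78e-14, adjusted p = 0.00412 with an estimated correlation). limma called 2186 of 5761 genes, 1091 up and 1095 down, of which 495 and 391 changed at least 2-fold.

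In KCl the kcs1vip1 cells (n = 3) held ribosome biogenesis genes above wild type in KCl, LTV1 by 4.47 ± 0.65, MRD1 by 4.44 ± 0.77, BRX1 by 4.11 ± 0.41 and NOP7 by 4.04 ± 0.21. HSP30 was higher by 5.95 ± 1.17, and OAC1 (-6.13 ± 0.26), LEU1 (-5.37 ± 0.11) and LEU2 (-4.34 ± 0.07) were lower. The mitochondrially encoded OLI1 passed at -6.47 ± 8.32 (2 values), a spread wider than the mean, so its value rests on 1 array. Ribosome biogenesis genes rose in 105 of 110 cases with 5 not passing (106 adjusted over the list alone). Their median was 2.23 (fry adjusted p = 2.35e-11, adjusted p = 0.072 with an estimated correlation). Polymerase I and III genes rose in 19 of 23 cases, with 1 falling and 3 not passing, RPA135 by 3.67 ± 0.67 and RPA190 by 3.46 ± 0.68. Their median was 1.47 (fry adjusted p = 1.63e-10, adjusted p = 0.123 with an estimated correlation). Ribosomal protein genes rose in 58 of 135 cases with 77 not passing (53 adjusted over the list alone), RPL36A by 2.69 ± 1.25 (median 0.70, fry adjusted p = 0.007, adjusted p = 0.672 with an estimated correlation), a call lost without kcs1vip1 KCl replicate 1 (fry adjusted p = 0.163). Osmotic genes fell in 6 of 16 cases, with 1 rising and 9 not passing, DAK1 at -2.32 ± 0.29 and GRE2 at -1.47 ± 0.60 (median -0.48, fry adjusted p = 1.34e-06, adjusted p = 0.542 with an estimated correlation), and the common stress-induced list was not called (median -0.43). Of 7 a-cell specific genes 6 fell and 1 rose. Their median was -1.07 (fry adjusted p = 3.36e-11, adjusted p = 0.072 with an estimated correlation). Nitrogen genes fell in 16 of 26 cases, with 4 rising and 6 not passing, DAL1 at -3.22 ± 0.15 (median -0.73, fry adjusted p = 2.88e-06, adjusted p = 0.542 with an estimated correlation), and oxidative phosphorylation genes in 21 of 34 with 13 not passing (24 adjusted over the list alone). Their median was -0.92 (fry adjusted p = 0.000319, adjusted p = 0.646 with an estimated correlation). limma called 2913 of 5788 genes, 1434 up and 1479 down, and 1901 after scaling to the same spread.

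The kcs1vip1 difference from wild type changed between log growth and KCl in 1554 of 5714 genes, 768 upward and 786 downward, of which 581 and 477 changed at least 2-fold (differences are KCl minus log ± SE, n = 3 and 3). Upward went LTV1 (4.72 ± 0.48), NOP7 (4.59 ± 0.36), HCA4 (4.57 ± 0.73), URA7 (4.50 ± 0.55), DHR2 (4.49 ± 0.70), HXT4 (4.40 ± 0.63), a glucose transporter gene, AAH1 (4.30 ± 0.40), MRD1 (4.27 ± 0.50), RPA43 (4.21 ± 0.44) and NOP13 (4.21 ± 0.52). Downward went HSP12 (-6.31 ± 0.96), HSP26 (-5.86 ± 0.81), TDH1 (-5.16 ± 0.72), HXT5 (-4.75 ± 0.54), DDR2 (-4.41 ± 1.11), SPI1 (-4.41 ± 0.46), TKL2 (-4.02 ± 0.36), MSC1 (-3.88 ± 0.45), SOL4 (-3.82 ± 0.57) and SIT1 (-3.79 ± 0.56). Ribosome biogenesis genes went up in 101 of 110 cases with 9 not passing (104 adjusted over the list alone, median 2.51, fry adjusted p = 1.73e-09, adjusted p = 0.0371 with an estimated correlation), and polymerase I and III genes in 17 of 23 with 6 not passing (19 adjusted over the list alone). Their median was 1.37 (fry adjusted p = 5.82e-09, adjusted p = 0.0435 with an estimated correlation). Common stress-induced genes went down in 44 of 62 cases, with 2 up and 16 not passing (47 and 2 adjusted over the list alone). Their median was -1.70 (fry adjusted p = 6.96e-06, adjusted p = 0.251 with an estimated correlation). Osmotic genes went down in 7 of 15 cases with 8 not passing (7 down and 1 up adjusted over the list alone), ALD3 at -3.09 and DAK1 at -2.88. Their median was -1.68 (fry adjusted p = 1.94e-05, adjusted p = 0.266 with an estimated correlation). Gcn4 targets went up in 19 of 36 cases with 17 not passing (20 adjusted over the list alone, median 0.91, fry adjusted p = 0.000657, adjusted p = 0.335 with an estimated correlation), and phosphate genes in 8 of 17 with 9 not passing (9 adjusted over the list alone), PHO89 by 3.62. Their median was 1.82 (fry adjusted p = 0.0111, adjusted p = 0.458 with an estimated correlation). Iron genes went down in 11 of 23 cases, with 1 up and 11 not passing (11 and 2 adjusted over the list alone). Their median was -0.87 (fry adjusted p = 0.000189, adjusted p = 0.266 with an estimated correlation). Leaving out any 1 array left between 1201 and 1633 genes, and scaling left 979. DHR2 was lost after scaling (limma adjusted p = 0.0884).

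Ribosome biogenesis and stress-induced genes also moved less on the single array that compared kcs1vip1 cells in KCl directly with kcs1vip1 cells in log growth. The median of ribosome biogenesis genes was -1.84 there against -4.20 ± 0.27 in wild type (n = 3), a share of 0.44, and that of polymerase I and III genes -1.50 against -2.90 ± 0.29, a share of 0.52. Common stress-induced genes stood at 3.58 against 4.49 ± 0.25, a share of 0.80, while osmotic genes stood at 7.30 against 6.75 ± 0.26, a share of 1.08. STL1 (15.58), CTT1 (11.20), ALD3 (10.76), DDR2 (10.28) and PHM7 (9.15) were the highest values on this array, and LSM4 (-3.84), PWP2 (-3.71), PHO84 (-3.65), PUF6 (-3.49) and NSR1 (-3.46) the lowest, with no test. Over the 1088 genes that fell at least 2-fold in wild type KCl and were measured here the slope on wild type was 0.48, and 1006 of them fell less. Over the 1038 that rose the slope was 0.78, and 856 rose less.

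The slope of each mutant's KCl minus log difference on wild type KCl was taken over the 2138 genes that changed at least 2-fold there. A slope below 0 can come from KCl or from genes already shifted in log growth. For genes that fell in wild type the slope was -0.58 ± 0.07 in kcs1vip1 (n = 3), -0.38 ± 0.01 in Rpd3ibs (n = 2), -0.27 ± 0.02 in arg82 (n = 3), -0.19 ± 0.15 in ipk1 (n = 3), -0.18 ± 0.07 in Vip1D487A (n = 2), -0.13 ± 0.05 in kcs1 (n = 2), -0.06 ± 0.04 in vip1 (n = 3) and -0.02 ± 0.01 in snt1 (n = 2), and -0.71 on the single rpd3 array. For genes that rose it was -0.38 ± 0.06 in kcs1vip1, -0.24 ± 0.02 in Rpd3ibs, -0.09 ± 0.01 in arg82, -0.07 ± 0.16 in ipk1, -0.07 ± 0.03 in Vip1D487A, -0.03 ± 0.02 in kcs1, 0.05 ± 0.01 in vip1, 0.01 ± 0.02 in snt1 and -0.48 on the rpd3 array. The ipk1 slopes include log and KCl replicate 2, whose labels are in doubt, and without the 5 doubted arrays the falling one was -0.21. With the fixed lists in place of these genes the rising slope of Rpd3ibs was -0.15, and with the sign of its dye swaps turned the falling slope of Vip1D487A was -0.09.

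**Figure D1:**
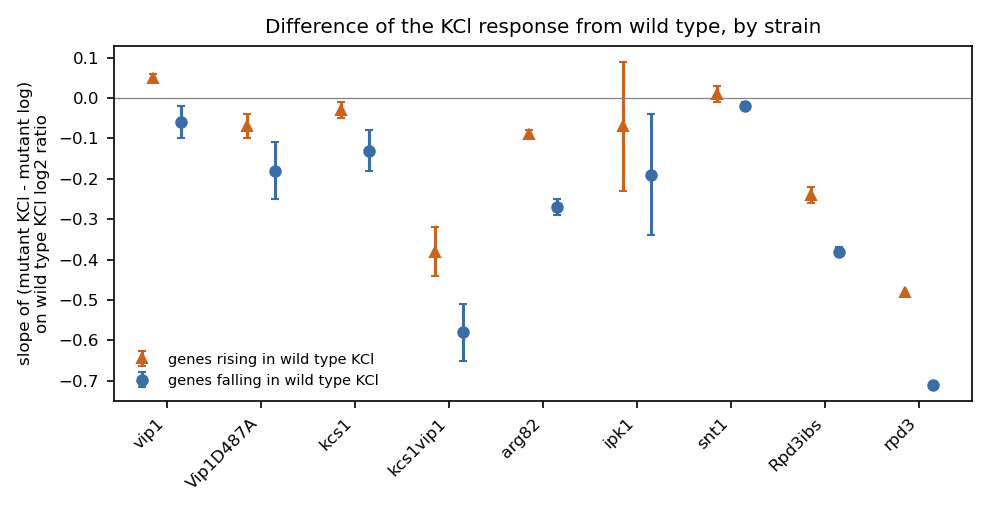
Slope of each mutant's KCl minus log difference on the wild type KCl response (mean ± SD, rpd3 n = 1). Genes that rose and genes that fell at least 2-fold in wild type are apart.

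Across genes, the KCl profile of kcs1vip1 had r = 0.69 with arg82, 0.61 with ipk1, 0.61 with vip1, 0.54 with kcs1, 0.49 with Rpd3ibs, 0.48 with Vip1D487A, 0.42 with rpd3 and 0.22 with snt1. In log growth these were 0.58 with arg82, 0.37 with ipk1, 0.08 with vip1, 0.52 with kcs1, 0.33 with Rpd3ibs, 0.36 with Vip1D487A, 0.39 with rpd3 and 0.41 with snt1. Genes are not independent replicates, and the labels do not say whether these arrays shared wild type RNA, from which a part of each r would come. The r of Rpd3ibs and rpd3 was 0.81 in KCl and 0.78 in log growth, and that of arg82 and kcs1 in KCl was 0.76. With a dye term the r of kcs1vip1 and snt1 turned to -0.02. Without replicate 1 of Vip1D487A the r of kcs1vip1 and Vip1D487A was 0.07 in log growth and 0.07 in KCl. That with kcs1 in log growth was 0.25 without kcs1 log replicate 1, which leaves the array whose label is in doubt, and that with arg82 was 0.48 without kcs1vip1 log replicate 1.

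Against its single mutants in KCl, kcs1vip1 (n = 3) held ribosome biogenesis genes higher than vip1 (n = 3) in 75 of 110 cases with 35 not passing (87 adjusted over the list alone). Their median was 1.54 (fry adjusted p = 1.64e-05, adjusted p = 0.0894 with an estimated correlation). PHO89 (5.04), PHO84 (4.25) and PUT1 (3.88) were higher than in vip1, and OAC1 (-5.09), LEU1 (-4.57) and the heat shock gene SSA4 (-4.53) lower. Phosphate genes were higher in 11 of 17 cases with 6 not passing (12 higher and 2 lower adjusted over the list alone). Their median was 1.58 (fry adjusted p = 0.0084, adjusted p = 0.354 with an estimated correlation). Against kcs1 (n = 2) ribosome biogenesis genes were higher in 80 of 110 cases with 30 not passing (90 adjusted over the list alone, median 1.73, fry adjusted p = 2.11e-05, adjusted p = 0.154 with an estimated correlation), PDH1 (4.05), FIT2 (3.81) and NOP7 (3.71) were higher, and PHM6 (-5.10), OAC1 (-4.56) and ARO10 (-4.28) lower. Phosphate genes were lower than in kcs1 in 8 of 17 cases with 9 not passing (13 adjusted over the list alone, fry adjusted p = 0.00851, adjusted p = 0.348 with an estimated correlation). limma called 906 of 5714 genes against vip1, 521 up and 385 down, and 875 of 5728 against kcs1, 551 up and 324 down. The phosphate call against kcs1 was lost without kcs1 KCl replicate 1 (fry adjusted p = 0.0876), where the count of genes was 188. PHM6 did not pass without either kcs1 array (limma adjusted p = 0.118 and 0.0843), the count without replicate 2 was 546, and scaling left 355 against vip1 and 383 against kcs1.

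Phosphate starvation genes moved in different directions in the kinase mutants. The list rose in kcs1 in KCl (n = 2) in 12 of 17 cases with 5 not passing (13 adjusted over the list alone), PHO89, a sodium-phosphate cotransporter gene, by 5.39 ± 0.04, PHO84 by 5.32 ± 0.71 and PHM6 by 5.04 ± 0.21. Their median was 2.20 (fry adjusted p = 0.000255, adjusted p = 0.133 with an estimated correlation). In arg82 in KCl (n = 3) they rose in 14 of 17 cases with 3 not passing, PHO89 by 6.21 ± 0.32, PHO84 by 4.88 ± 0.64 and SPL2 by 3.67 ± 0.31. Their median was 1.87 (fry adjusted p = 6.38e-05, adjusted p = 0.243 with an estimated correlation). In arg82 in log growth (n = 2) 4 of 17 rose and 13 did not pass (5 adjusted over the list alone, median 0.94, fry adjusted p = 0.0632, not called). In ipk1 in KCl (n = 3) 7 of 17 rose, 1 fell and 9 did not pass (9 and 2 adjusted over the list alone). Their median was 0.88 (fry adjusted p = 0.0452, adjusted p = 0.595 with an estimated correlation), and 0.10 without ipk1 KCl replicate 2, where the call was lost (fry adjusted p = 0.834), as it was with scaling (0.129). In vip1 they fell, in log growth (n = 2) in 12 of 17 cases with 5 not passing (12 and 1 rising adjusted over the list alone), PHM6 at -4.61 ± 0.52, PHO12 at -4.30 ± 0.49 and the acid phosphatase PHO5 at -4.29 ± 0.59. Their median was -1.53 (fry adjusted p = 0.000641, adjusted p = 0.322 with an estimated correlation). In vip1 in KCl (n = 3) 8 of 17 fell and 9 did not pass (11 adjusted over the list alone), PHO5 at -3.19 ± 0.41, PHO84 at -2.66 ± 0.60 and PHO11 at -2.39 ± 0.11. Their median was -1.19 (fry adjusted p = 0.00778, adjusted p = 0.375 with an estimated correlation). In kcs1vip1 in log growth they fell in 9 of 17 cases with 8 not passing, GIT1 at -3.63 ± 0.32. Their median was -0.78 (fry adjusted p = 0.00863, adjusted p = 0.555 with an estimated correlation, and fry adjusted p = 0.117 with a dye term). In kcs1vip1 in KCl 8 rose, 2 fell and 7 did not pass (median 0.47, fry adjusted p = 0.346, not called), while KCl minus log went up (median 1.82). The vip1 call was lost in log growth without replicate 1 (fry adjusted p = 0.061) and in KCl without 1 (0.0767) or 3 (0.0502). With a dye term PHO5, PHO84 and PHO11 did not pass in vip1 KCl (limma adjusted p = 0.18, 0.0622 and 0.069). Without either array PHM6 did not pass in kcs1 KCl (0.119 and 0.161) or vip1 log growth (0.214 and 0.0576).

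**Figure D2:**
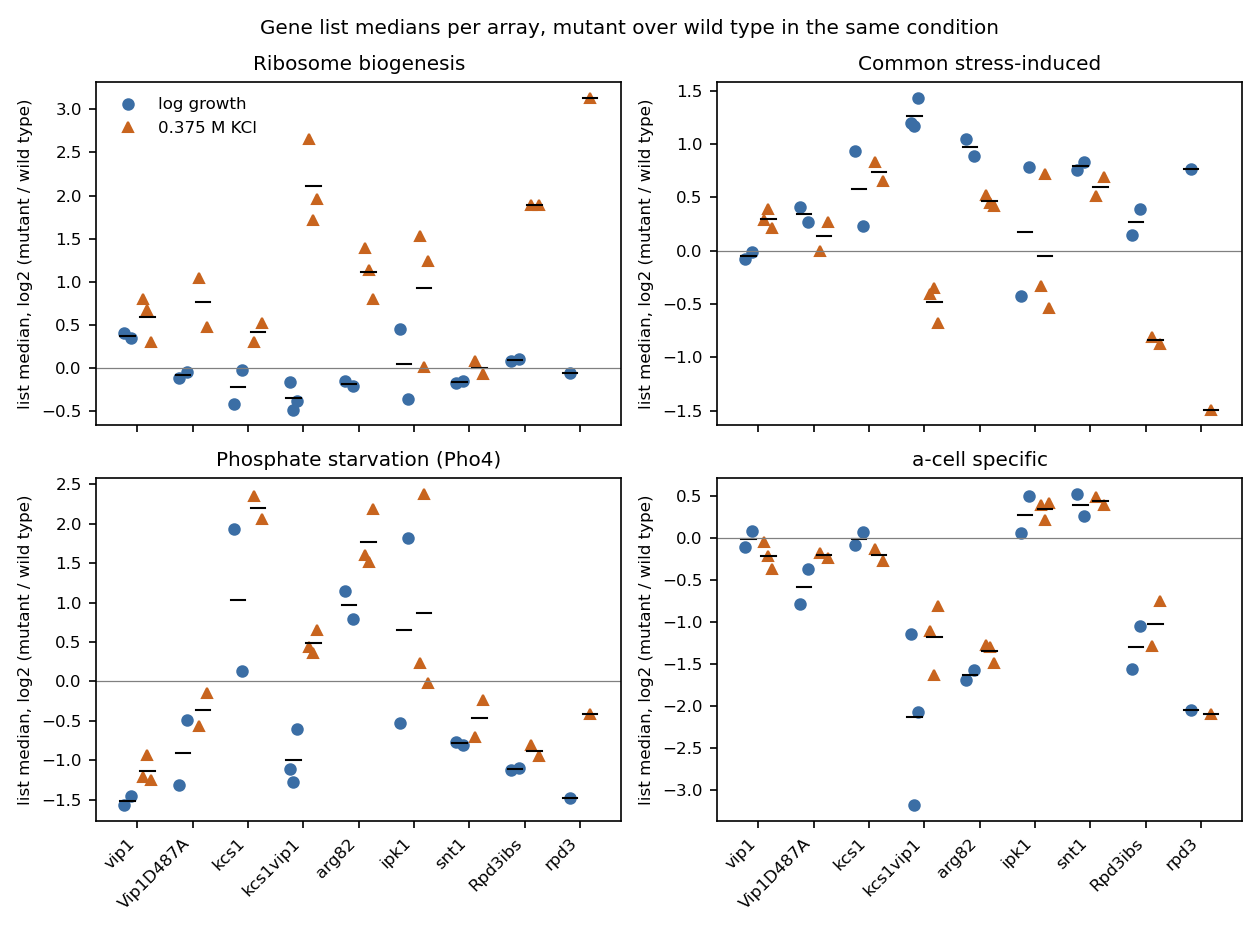
Median log2 ratio of the ribosome biogenesis, common stress-induced, phosphate starvation and a-cell specific lists on each array of each mutant over wild type.

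In arg82 cells the arginine synthesis gene ARG3 rose by 5.57 ± 0.35 in log growth (n = 2) and 4.96 ± 0.46 in KCl (n = 3), and ARG82 is a part of the ArgR/Mcm1 regulator. HSP12 (5.08 ± 0.30) and PHO89 (4.79 ± 0.12) rose in log growth, and CAR2 (-3.33 ± 0.22), FUR1 (-3.05 ± 0.03) and OAC1 (-2.75 ± 0.09) fell. In KCl HSP30 rose by 5.29 ± 0.52, and BAR1 (-3.95 ± 0.19), SNZ3 (-3.52 ± 0.27, 2 values) and OAC1 (-3.09 ± 0.31) fell. Ribosome biogenesis genes were higher than in wild type in KCl in 78 of 111 cases with 33 not passing (82 adjusted over the list alone), MRD1 by 2.89 ± 0.44 and BRX1 by 2.63 ± 0.10. Their median was 1.10 (fry adjusted p = 8.86e-06, adjusted p = 0.209 with an estimated correlation). The arginine list in KCl had 4 genes that rose, 5 that fell and 1 that did not pass (4 and 6 adjusted over the list alone), with a median of -0.44, a mean of 1.08 and the fry direction up (adjusted p = 9.24e-05, adjusted p = 0.729 with an estimated correlation). Of 7 a-cell specific genes in KCl 6 fell and 1 rose, STE6 at -2.05 ± 0.13 (median -1.40, fry adjusted p = 1.15e-11, adjusted p = 0.0108 with an estimated correlation), and in log growth 5 of 6 fell and 1 did not pass. Their median was -1.68 (fry adjusted p = 4.77e-08, adjusted p = 0.0213 with an estimated correlation). In the KCl minus log difference CPA1 (3.63), HSP30 (3.52) and PHO84 (3.35) went up, HSP12 (-4.07), TDH1 (-2.98) and SIT1 (-2.57) went down, and 43 of 98 ribosome biogenesis genes went up with 55 not passing (71 adjusted over the list alone). Their median was 1.35 (fry adjusted p = 0.0014, adjusted p = 0.0538 with an estimated correlation). limma called 893 of 5190 genes in log growth, 1858 of 5813 in KCl and 196 of 5130 in the difference. Without arg82 log replicate 1 or 2 the log count was 64 or 168 and that of the difference 27 or 32, where HSP12 (limma adjusted p = 0.334 and 0.241), HSP30 (0.0987 and 0.0746), PHO84 (0.088 and 0.166), TDH1 and SIT1 did not pass. TDH1 did not pass without any 1 KCl array either. Without replicate 1 PHO89 did not pass in log growth (0.056), without KCl replicates 1, 2 and 3 the difference had 118, 119 and 128 genes, and the KCl count was 969 and 946 without KCl replicates 1 and 2. A dye term left 413 in log growth and 830 in KCl, and with slide as a random block the difference had 362.

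In ipk1 cells LEU1 (-5.14 ± 1.29), LEU2 (-4.80 ± 0.45) and OAC1 (-4.55 ± 0.61) fell in log growth (n = 2), and OAC1 (-5.48 ± 0.56), LEU1 (-4.50 ± 0.86) and LEU2 (-3.84 ± 0.09) in KCl (n = 3). GAP1 (-4.33 ± 0.20) and MEP2 (-3.85 ± 0.50), of amino acid and ammonium uptake, fell in log growth, within a nitrogen list of 26 with 12 that fell and 14 that did not pass (13 adjusted over the list alone). Their median was -0.89 (fry adjusted p = 3.11e-05, adjusted p = 0.574 with an estimated correlation). CAR2 (2.60 ± 0.42) rose in log growth, and HOR7 (4.17 ± 4.01 and 4.30 ± 4.00) and DDR2 (2.69 ± 3.59 and 2.53 ± 3.95) passed in log growth and KCl with a spread as wide as the mean. The labels of ipk1 log and KCl replicate 2, which share a slide, are in doubt. The r of the log arrays was 0.35, and KCl replicate 2 had 0.09 and 0.16 with the other KCl arrays, which had 0.78 with each other. Without replicate 2, HOR7 in log growth was 1.33 (limma adjusted p = 0.533) and DDR2 was 0.15 in log growth and 0.26 in KCl. PHM6 (2.73 ± 4.55) passed in KCl and was 0.10 without KCl replicate 2. Ribosome biogenesis genes were higher in KCl in 72 of 111 cases with 39 not passing (77 adjusted over the list alone). Their median was 0.99 (fry adjusted p = 0.000177, adjusted p = 0.271 with an estimated correlation). limma called 1397 of 5622 genes in log growth, 1367 of 5753 in KCl and 1 of 5553 in the difference, ALD5 (2.12, SE 0.33), with 517 at unadjusted p < 0.05. Without ipk1 log replicate 2 the log count was 32 and the difference 0, CAR2 did not pass there (limma adjusted p = 0.0579), without log replicate 1 the difference was 347, and without KCl replicate 2 it was 698. With slide as a random or a fixed block it was 17 or 0. A dye term left 411 in log growth and 168 in KCl, where HOR7, DDR2 and PHM6 did not pass (limma adjusted p = 0.086, 0.33 and 0.145 in KCl).

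In vip1 cells ribosomal protein genes rose in log growth (n = 2) in 55 of 71 cases, with 1 falling and 15 not passing (60 and 2 adjusted over the list alone), RPL21A by 4.43 ± 0.18, RPL41A by 4.30 ± 0.76 and RPL39 by 4.06 ± 0.40. Only 71 of 135 were tested, which may not represent the list. Their median was 1.79 (fry adjusted p = 0.000155, adjusted p = 0.243 with an estimated correlation). In KCl (n = 3) HSP30 (3.95 ± 0.21), the stress gene BTN2 (2.69 ± 0.46) and HXT7 (2.47 ± 0.17) rose. In the KCl minus log difference HSP30 (4.76), HXT7 (2.83) and HXT2 (2.71) went up, and VAR1 (-5.04), RPL21A (-4.75) and AI5_BETA (-3.29) went down. VAR1 and AI5_BETA are mitochondrial, and their chromosome median, less that of the array, was 2.04 and 0.86 on the vip1 log arrays. Arginine genes fell in log growth in 7 of 10 cases with 3 not passing, ARG1 at -2.50 ± 0.37. Their median was -1.08 (fry adjusted p = 6.81e-05, adjusted p = 0.243 with an estimated correlation). limma called 1038 of 5437 genes in log growth, 542 of 5763 in KCl and 306 of 5390 in the difference. These counts were 62 and 7 (log growth and difference) without log replicate 1, 309 and 50 without 2, 73 and 75 (KCl and difference) without KCl replicate 1, 132 and 165 without 2, and 181 and 142 without 3. Without log replicate 1 ribosomal proteins were not called (fry adjusted p = 0.0521), nor was RPL39 (limma adjusted p = 0.0751). Without either log array HXT7, HXT2 and AI5_BETA did not pass in the difference (0.0972 and 0.0997, 0.19 and 0.193, 0.126 and 0.0588). The difference had 817 or 807 with slide as a random or fixed block and 818 with scaling. KCl had 1844 with scaling and 61 with a dye term.

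On the arrays labelled kcs1 (n = 2 each) LEU1 (-2.53 ± 0.30) and OAC1 (-2.44 ± 0.56) fell in log growth, and PMP1 (2.33 ± 0.45), PGK1 (2.19 ± 0.95), a glycolysis gene, and CCW12 (2.08 ± 0.52) rose. KCS1 passed at -2.79 ± 3.53 and was -0.30 on the array labelled kcs1 log replicate 2 alone (limma adjusted p = 0.943), whose label is in doubt, since IPK1 was -2.87 there and its r with replicate 1 was 0.14. In KCl IMD2 (-3.47 ± 0.25), BAR1 (-3.35 ± 0.63) and FRE7 (-2.54 ± 0.31) fell. limma called 26 of 5912 genes in log growth, 611 at unadjusted p < 0.05, 459 of 5756 in KCl and 0 of 5705 in the difference, 427 at unadjusted p < 0.05, and no list was called in log growth. Without log replicate 1 the counts were 9 in log growth and 43 in the difference, and without KCl replicates 1 and 2 the KCl count was 57 and 22. PMP1 (limma adjusted p = 0.137 and 0.241), CCW12 (0.23 and 0.335), IMD2 (0.352 and 0.247) and FRE7 (0.0681 and 0.164) did not pass without either array, nor BAR1 without KCl replicate 2 (0.0942), nor PGK1 and LEU1 without log replicate 2 (0.187 and 0.0615). With a dye term KCS1, PMP1, PGK1, CCW12, IMD2 and FRE7 did not pass (limma adjusted p = 0.145, 0.208, 0.242, 0.694, 0.146 and 0.059). Scaling gave 448 in log growth, 1178 in KCl and 39 in the difference.

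In Rpd3ibs cells (n = 2 each), BNA1 (-6.57 ± 0.54) and BNA5 (-4.62 ± 0.31), of NAD synthesis, fell in log growth and BNA1 (-6.49 ± 0.38) and BNA2 (-6.03 ± 0.45) in KCl. PYK2 (-4.28 ± 0.24) fell and TKL2 (3.37 ± 0.07), BUD25 (3.02 ± 0.40) and SSA4 (2.97 ± 0.42) rose in log growth. In KCl DAL4 (-5.82 ± 0.59), of the nitrogen list, fell. NSR1 (3.17 ± 0.01), RRS1 (3.09 ± 0.07) and DHR2 (3.06 ± 0.16) were higher than in wild type in KCl, among 101 of 111 ribosome biogenesis genes with 10 not passing (104 adjusted over the list alone). Their median was 1.91 (fry adjusted p = 1.06e-07, adjusted p = 0.12 with an estimated correlation). Common stress-induced genes were lower in KCl in 25 of 62 cases, with 1 higher and 36 not passing (28 and 1 adjusted over the list alone), ECM4 at -2.85 ± 0.08 and GND2 at -2.67 ± 0.19. Their median was -0.88 (fry adjusted p = 0.000432, adjusted p = 0.374 with an estimated correlation). Polymerase I and III genes were higher in 14 of 23 cases with 9 not passing (17 adjusted over the list alone). Their median was 1.04 (fry adjusted p = 1.48e-06, adjusted p = 0.124 with an estimated correlation). Of 7 a-cell specific genes 6 fell in log growth and 1 did not pass, BAR1 at -3.88 ± 0.83. Their median was -1.38 (fry adjusted p = 3.76e-08, adjusted p = 0.0216 with an estimated correlation). Of 24 nitrogen genes in KCl 11 fell and 13 did not pass (12 adjusted over the list alone), OPT2 at -3.66 ± 0.37 and UGA4 at -3.31 ± 0.11 (median -0.83, fry adjusted p = 1.48e-06, adjusted p = 0.124 with an estimated correlation).

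In the Rpd3ibs KCl minus log difference ribosome biogenesis genes went up in 76 of 111 cases with 35 not passing (101 adjusted over the list alone), NSR1 by 2.71 and DBP3 by 2.61. Their median was 1.78 (fry adjusted p = 0.000196, adjusted p = 0.0386 with an estimated correlation). Polymerase I and III genes went up in 7 of 23 cases with 16 not passing (11 adjusted over the list alone). Their median was 1.12 (fry adjusted p = 0.000329, adjusted p = 0.0535 with an estimated correlation). Stress-induced genes went down in 14 of 60 cases, with 1 up and 45 not passing (27 and 1 adjusted over the list alone). Their median was -0.95 (fry adjusted p = 0.00736, adjusted p = 0.194 with an estimated correlation). TKL2 (-4.29), XBP1 (-2.73), a repressor gene, and PHM7 (-2.72) went down, and the transporter MMP1 (2.90), HXT4 (2.83) and STR3 (2.79), of sulfur metabolism, went up. limma called 1144 of 5597 genes in log growth, 1810 of 5674 in KCl and 382 of 5565 in the difference. Without log replicates 1 and 2 the counts were 410 and 673 in log growth and 107 and 182 in the difference, and without KCl replicates 1 and 2 they were 903 and 923 in KCl and 94 and 122 in the difference. The stress-induced call was lost without log replicate 2 or KCl replicate 2 (fry adjusted p = 0.0588 and 0.0855), MMP1 and STR3 did not pass without any 1 of the 4 arrays, HXT4 without either log array or KCl replicate 1 (limma adjusted p = 0.113, 0.0998 and 0.231) and XBP1 without log replicate 1 or KCl replicate 2 (0.111 and 0.088). With slide as a random or a fixed block the difference had 756 or 686 genes and with scaling 225, and a dye term left 667 in log growth and 1151 in KCl.

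On the single rpd3 arrays (n = 1, no test) ribosome biogenesis genes had a median of 3.13 in KCl, above every random list of the same size, with 100 of 108 at least 2-fold up, and -0.05 in log growth. DHR2 (7.57), RRP12 (6.00), SRT1 (5.90), HCA4 (5.90) and MRD1 (5.80) were highest in KCl, and BNA1 (-7.22), BNA2 (-5.85), BNA5 (-5.12), GPM2 (-5.11) and BAR1 (-4.90) lowest. The common stress-induced median was 0.77 in log growth and -1.49 in KCl. Meiotic genes, which Rpd3 represses with Ume6, had medians of 1.80 in log growth and 1.85 in KCl, and a-cell specific genes -2.04 and -2.09. In log growth INO1 (6.54), RTA1 (5.14), SHC1 (5.02), SRT1 (4.87) and HSP30 (4.76) were highest, and BNA1 (-6.85), PHM6 (-5.80), BNA2 (-5.75), SNZ2 (-5.51) and PYK2 (-5.02) lowest.

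In snt1 cells (n = 2 each) LEU1 (-4.96 ± 0.37), LEU2 (-4.67 ± 0.48) and OAC1 (-4.64 ± 0.08) fell in log growth, and OAC1 (-6.13 ± 0.39), LEU1 (-4.17 ± 0.69) and LEU2 (-3.65 ± 0.47) in KCl. DDR2 (3.42 ± 0.23), BUD25 (2.88 ± 1.07) and HXT7 (2.65 ± 0.76) rose in log growth, and HSP30 (2.62 ± 0.01), BUD25 (2.48 ± 1.04) and the alpha-factor gene MF(ALPHA)2 (2.02 ± 1.14) in KCl. Gcn4 targets fell in 12 of 36 cases with 24 not passing in log growth (16 falling and 1 rising adjusted over the list alone, median -0.62, fry adjusted p = 0.00937, adjusted p = 0.566 with an estimated correlation) and in 12 of 36 in KCl (17 adjusted over the list alone). Their median was -0.67 (fry adjusted p = 0.00284, adjusted p = 0.394 with an estimated correlation). Ribosome biogenesis genes were level with wild type in KCl (array medians 0.00 ± 0.11). limma called 575 of 5569 genes in log growth, 451 of 5733 in KCl and 0 of 5536 in the difference, 168 at unadjusted p < 0.05. Without snt1 log replicates 1 and 2 the log count was 105 and 32, and Gcn4 targets were not called (fry adjusted p = 0.0968 and 0.311). Without KCl replicates 1 and 2 the KCl count was 15 and 70, BUD25 (limma adjusted p = 0.0732 and 0.293), HSP30 (0.187 and 0.118) and MF(ALPHA)2 (0.0541 and 0.374) did not pass, and Gcn4 targets were not called without replicate 2 (fry adjusted p = 0.171). DDR2 did not pass without either log array (limma adjusted p = 0.211 and 0.326), and BUD25 did not without log replicate 2 (0.244) and HXT7 did not without log replicate 1 (0.106). Scaling gave 1291 in log growth and 1276 in KCl, and a dye term 67 and 49.

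In Vip1D487A cells (n = 2 each), whose label names a substitution in Vip1, the ammonium permease gene MEP2 fell by 1.89 ± 0.61 in log growth, 1 of 2 genes that limma called of 5571 (416 at unadjusted p < 0.05). In KCl HSP30 (3.22 ± 1.23), ROK1 (2.23 ± 0.55), a ribosome assembly helicase gene, and CIN5 (2.06 ± 0.54) rose, and DAL1 (-1.57 ± 0.42), LSM6 (-1.45 ± 1.02) and DIC1 (-1.40 ± 0.35) fell. Ribosome biogenesis genes rose in KCl in 27 of 105 cases with 78 not passing (50 adjusted over the list alone). Their median was 0.72 (fry adjusted p = 0.0368, adjusted p = 0.391 with an estimated correlation). No arginine gene of 10 passed in log growth, while 6 fell adjusted over the list alone. Their median was -0.79 (fry adjusted p = 0.0106, adjusted p = 0.062 with an estimated correlation). limma called 121 of 5624 genes in KCl, 89 up and 32 down, and 0 of 5467 in the difference, 295 at unadjusted p < 0.05. Scaling gave 654 genes in log growth, 43.7% of them up, 449 in KCl, 59.2% of them up (73.6% before), and 18 in the difference. Without KCl replicate 1, which leaves the dye-swapped array, the KCl count was 16, HSP30, CIN5, DAL1 and DIC1 did not pass (limma adjusted p = 0.207, 0.137, 0.288 and 0.138) and ribosome biogenesis was not called (fry adjusted p = 0.661). Without KCl replicate 2 ROK1 and LSM6 did not pass (0.0845 and 0.458). Without log replicate 1 the arginine call was lost (fry adjusted p = 0.847), as was MEP2 (limma adjusted p = 0.521), and the log count was 17, or 16 without log replicate 2. With the sign of the dye-swapped arrays turned the counts were 1 in log growth and 1 in KCl, none of the 7 named genes passed, and ROK1 was -0.39 and LSM6 0.72.

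The 2 arrays labelled kcs1vip1 over wild type in H2O2 showed HSP30 at 6.04 ± 1.68, MGA1 at 5.18 ± 1.94 and DAK2 at 4.41 ± 1.44, while RPS28B (-2.92 ± 0.13), HLR1 (-1.80 ± 0.47) and CLB2 (-1.79 ± 0.97) fell. LEU2, low in kcs1vip1 in log growth and KCl, stood at 2.38 ± 1.15. Oxidative stress genes rose in 7 of 21 cases with 14 not passing (11 adjusted over the list alone), GPX2 by 4.40 ± 1.87. Their median was 0.65 (fry adjusted p = 5.49e-05, adjusted p = 0.043 with an estimated correlation). Heat shock genes rose in 7 of 24 cases with 17 not passing (10 rising and 1 falling adjusted over the list alone). Their median was 0.58 (fry adjusted p = 0.000961, adjusted p = 0.114 with an estimated correlation). limma called 293 of 5831 genes, 195 up and 98 down. Without replicate 1 the count was 20, and the oxidative (fry adjusted p = 0.197) and heat shock (0.415) calls were lost, as were HLR1 (limma adjusted p = 0.132) and CLB2 (0.169). Scaling gave 1130.

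Compared with kcs1vip1 in log growth, these arrays differed in 921 of 5732 genes, LEU2 by 6.56, OAC1 by 5.95 and LEU1 by 5.65 upward and HSP12 by -6.32, FIT2 by -5.40 and PIR3 by -4.59. Of 7 a-cell specific genes 6 went up and 1 did not pass (median 2.22, fry adjusted p = 4.76e-09, adjusted p = 0.00473 with an estimated correlation), and of 36 Gcn4 targets 23 went up, 1 down and 12 did not pass (29 and 1 adjusted over the list alone). Their median was 1.16 (fry adjusted p = 3.48e-06, adjusted p = 0.0941 with an estimated correlation). Of 18 genes that marked kcs1vip1 in log growth, 17 were measured on each array labelled H2O2 or heat, without KCS1 on those labelled H2O2, and 17, 17 and 16 on the kcs1vip1 KCl arrays. Their slope was -0.03 and 0.00 on the 2 arrays labelled H2O2 and -0.11 on the array labelled heat, against 0.95, 0.93 and 0.90 on the kcs1vip1 KCl arrays. The count of the difference was 360 and 528 without replicates 1 and 2 of the arrays labelled H2O2, and 220 with slide as a fixed block.

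**Figure D3:**
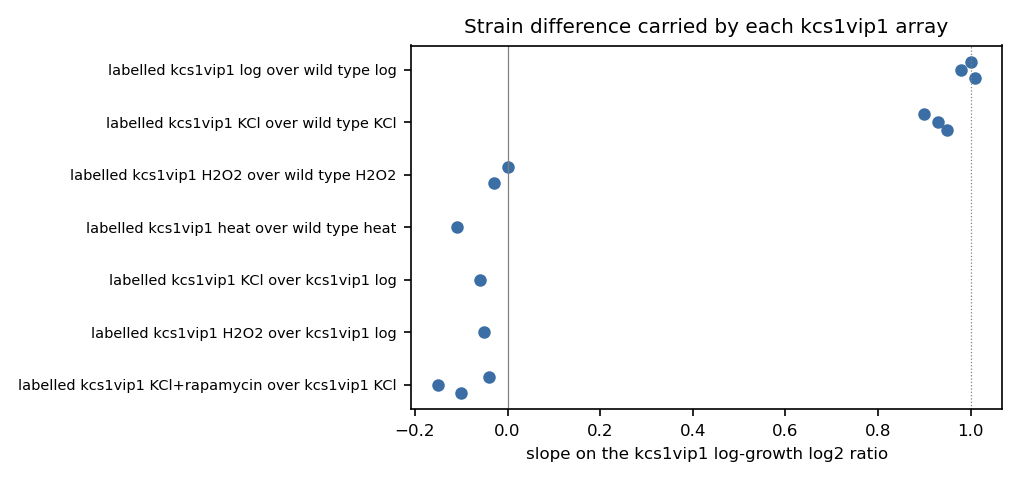
Slope of up to 18 genes on their kcs1vip1 log-growth log2 ratios for each array labelled kcs1vip1 in either channel.

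In heat at 42 °C (n = 1 each, no test) the wild type array had HSP30 at 9.39, SSA4 at 8.25 and HSP26 at 7.62, a heat shock median of 3.17 and a ribosome biogenesis median of -2.15, NSR1 at -4.73. The array labelled kcs1vip1 over wild type in heat had HSP30 at 9.82, SSA4 at 9.53, SPI1 at 9.34, HSP26 at 8.76 and BTN2 at 8.64, with medians of 3.18 for heat shock genes, 2.19 for common stress-induced genes and -0.44 for ribosome biogenesis genes. The array of kcs1vip1 in H2O2 over kcs1vip1 in log growth had HSP30 at 5.27, MGA1 at 4.63 and GPX2 at 3.47, with medians of 0.78 for oxidative stress genes, 0.60 for stress-induced genes and -0.15 for ribosome biogenesis genes.

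Rapamycin, which inhibits TORC1, raised genes of nitrogen uptake when added to kcs1vip1 cells in KCl (n = 3). GAP1 rose by 7.18 ± 1.03, MEP2 by 6.85 ± 1.14, AGP1 by 6.56 ± 0.68, DAL80 by 4.57 ± 0.88, PTR2 by 3.84 ± 0.35, DAL3 by 3.71 ± 1.02, DAL5 by 3.67 ± 1.09, UGA4 by 3.45 ± 1.13, GDH1 by 3.29 ± 1.36 and DIP5 by 3.27 ± 0.72. The largest falls of named genes were in purine genes, ADE17 (-2.14 ± 1.01), ADE4 (-1.87 ± 0.56) and HPT1 (-1.46 ± 0.24), in MTD1 (-1.73 ± 0.88), ILV5 (-1.72 ± 0.47), GCV1 (-1.60 ± 0.46) and URM1 (-1.45 ± 0.95), and in RPA12 (-1.69 ± 0.42), MAK16 (-1.47 ± 0.46) and RPA14 (-1.44 ± 1.02), of ribosome synthesis. Nitrogen catabolite genes rose in 21 of 26 cases with 5 not passing (23 adjusted over the list alone). Their median was 1.69 (fry adjusted p = 3.55e-14, adjusted p = 5.93e-06 with an estimated correlation). Polymerase I and III genes fell in 5 of 23 cases with 18 not passing (7 adjusted over the list alone). Their median was -0.52 (fry adjusted p = 0.00214, adjusted p = 0.245 with an estimated correlation). Retrograde genes rose in 3 of 9 cases with 6 not passing (5 adjusted over the list alone), CIT2 by 2.08 ± 0.47 (median 0.63, fry adjusted p = 0.00214, adjusted p = 0.245 with an estimated correlation), and mitochondrial ribosome genes fell in 5 of 57 with 52 not passing (11 adjusted over the list alone). Their median was -0.40 (fry adjusted p = 0.0198, adjusted p = 0.38 with an estimated correlation). limma called 306 of 6052 genes, 150 up and 156 down, of which 94 and 59 changed at least 2-fold. Without replicates 1, 2 and 3 the count was 185, 78 and 222, and without replicate 2 the polymerase (fry adjusted p = 0.15) and mitochondrial ribosome (0.326) calls were lost, as were MAK16 (limma adjusted p = 0.445) and ADE17 (0.553), while the retrograde call was lost without replicate 3 (fry adjusted p = 0.0586). MAK16 and ADE17 did not pass without replicate 1 or 3 either, nor URM1 without replicate 1 or 2 (limma adjusted p = 0.0993 and 0.622), nor ILV5 and RPA14 without replicate 2 (0.0525 and 0.244). Scaling gave 1643 genes.

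On the single array of wild type with rapamycin in log growth (n = 1, no test, array median 0.38) the nitrogen median was 3.64, with DAL5 (6.52), UGA4 (5.93), DAL80 (5.76), PDC6 (5.69) and DAL4 (5.66) highest. Ribosome biogenesis genes stood at -3.64, ribosomal protein genes at -1.52 and polymerase I and III genes at -2.46, with PUF6 (-6.73), UTP13 (-6.71), PWP1 (-6.61), NSR1 (-6.42) and DBP3 (-6.02) lowest.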

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

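Every test in this part was written after the result it weighs had been seen, except the 2 counts over splits of the arrays, which were set before.

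LEU2, low in kcs1vip1 in log growth and KCl, was 2.38 ± 1.15 on the 2 arrays labelled kcs1vip1 over wild type in H2O2 and 1.47 on the array labelled heat. The signature genes (16 to 18 of 18 measured on an array) had a mean slope of -0.05 over these 3 arrays, where the kcs1vip1 KCl arrays had 0.90 to 0.95 and arrays with kcs1vip1 in both channels -0.15 to -0.04. VIP1, deleted in this strain, was -0.01 on the array labelled heat, which goes against heat ending the strain difference, and with 0 values of KCS1 and VIP1 on the arrays labelled H2O2 the same cannot be said there. Replicates 1 and 2 labelled H2O2 had an r of 0.67 and 0.60 with kcs1vip1 in H2O2 over kcs1vip1 in log growth, and the array labelled heat 0.77 with wild type heat over log growth. These arrays may carry 1 strain in both channels, under stress over log growth, and the 921 genes of the difference between the arrays labelled H2O2 and kcs1vip1 in log growth might then hold strain and H2O2 together.

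LTV1, NOP7 and MRD1, of ribosome biogenesis, were among the 1554 genes whose kcs1vip1 difference changed between log growth and KCl. Within a slide the KCl minus log difference of their list was at least 2.20, which leaves little room for a slide effect. On the direct array (kcs1vip1 KCl over log) the list median was -1.84, above all 3 wild type arrays. Osmotic genes kept a share of the wild type response higher by 0.64. Both values rest on 1 array. The array without a group, titled alike but with KCl in both sources, had medians of -1.62 and 6.45 (osmotic). With its label unclear and osmotic genes at a median of -1.68 in the difference, another wild type RNA and a weaker stress in the mutant stay open. Of 10 splits of the 6 arrays the real one gave 1554 genes, the next 488, and so few splits cannot rule out chance.

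HSP30 rose by 3.22 ± 1.23 in Vip1D487A in KCl, but the dye-swapped array of each pair did not resemble its partner. The r across genes with the partner was 0.02 in log growth and 0.15 in KCl, near 0 in either sign, while a dye-swapped wild type KCl array had 0.89 and 0.91 with its partners as deposited. That sign was therefore turned, and whether those of the Vip1D487A arrays were stays open. The 2 swapped arrays, which share a slide, had an r of 0.60 and the unswapped pair 0.52, so this cannot show a slide effect. A slide or dye difference in Vip1D487A values stays open.

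Other counts of differing genes were 1 for ipk1 (ALD5), 196 for arg82, 306 for vip1 and 382 for Rpd3ibs between KCl and log growth, and 906 and 875 for kcs1vip1 against vip1 and kcs1 in KCl. Of 10 splits the real one gave the 906 and every other 0. On the array without a group the common stress-induced median was 3.29.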

How the results depend on the processing

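The alternatives that turn the Vip1D487A swaps, leave out 5 doubted arrays or keep exact zeros were chosen after the results were seen. No paired analysis was possible by replicate number because the labels carry no replicate numbers that link arrays of different groups.

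In wild type KCl and kcs1vip1 KCl minus log the ribosome biogenesis and stress-induced calls held with centring, scaling and slide as a random block. They held without the doubted arrays or any 1 array. A dye term kept the wild type calls and cancels from the difference (no swaps). Camera lost the stress-induced call of the difference. Of 257 list calls fry made, camera with an estimated correlation kept 21, a dye term 200, scaling 224, leaving out the doubted arrays 239, slide as a random block 244 and centring 250. Of named gene calls scaling lost 30 and kept 231, and a dye term lost 38 and kept 220. Leaving out 1 array, counted per gene and array, lost 152 calls and kept 676.

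With centring the snt1 difference between KCl and log growth (called the difference below) went from 0 to 1. With scaling to the same spread counts were 2169 (from 3571) in wild type KCl, 1510 (from 2490) in wild type H2O2, 663 (1397) in ipk1 log, 448 (26) in kcs1 log, 1291 (575) in snt1 log, 654 (2) in Vip1D487A log, 1901 (2913) in kcs1vip1 KCl, 1844 (542) in vip1 KCl, 1178 (459) in kcs1 KCl, 1276 (451) in snt1 KCl and 449 (121) in Vip1D487A KCl. For the difference they were 0 (1) in ipk1, 979 (1554) in kcs1vip1, 818 (306) in vip1, 39 (0) in kcs1, 5 (0) in snt1, 18 (0) in Vip1D487A and 225 (382) in Rpd3ibs. They were 1130 (293) on the arrays labelled kcs1vip1 in H2O2, 1643 (306) with rapamycin, 355 (906) against vip1 and 383 (875) against kcs1. The percent of called genes that rose moved from 0 to 43.7 in Vip1D487A log, from 73.6 to 59.2 in Vip1D487A KCl and from 66.6 to 52.0 on the arrays labelled H2O2.

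With only genes on every array counts were 6 in kcs1 log, 1 in Vip1D487A log and 4 in the kcs1 difference. With slide as a random block they were 43 in kcs1 log and 1 in Vip1D487A log, and in the difference 17 in ipk1, 362 in arg82, 817 in vip1, 6 in kcs1, 3 in snt1, 4 in Vip1D487A and 756 in Rpd3ibs. With slide as a fixed block, estimable for 11 comparisons, the difference had 0 in ipk1, 807 in vip1, 4 in snt1, 1 in Vip1D487A and 686 in Rpd3ibs, and the arrays labelled H2O2 minus log 220. Robust moderation (31 counts), a coefficient per RNA source (10) and kept zeros (3) left each count they were run on within 1.5 times.

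With a dye term (resting in part on doubted swaps) log counts were 411 in ipk1, 413 in arg82, 5 in kcs1, 67 in snt1, 10 in Vip1D487A and 667 in Rpd3ibs. KCl counts were 168 in ipk1, 830 in arg82, 61 in vip1, 105 in kcs1, 49 in snt1 and 1151 in Rpd3ibs, the difference had 2 in kcs1 and 1 in snt1, and the arrays labelled H2O2 had 178. The r of kcs1vip1 in KCl went from 0.61 to 0.50 with vip1, 0.22 to -0.02 with snt1 and 0.49 to 0.39 with Rpd3ibs. In log growth that with snt1 went from 0.41 to 0.32. In KCl vip1 and kcs1 went from 0.52 to 0.36 and ipk1 and vip1 from 0.64 to 0.46. With the fixed lists the rising slopes of Rpd3ibs and rpd3 went from -0.24 to -0.15 and from -0.48 to -0.39. Over genes past the threshold in either comparison the r of kcs1vip1 and rpd3 in KCl was 0.53, and that of Rpd3ibs and rpd3 0.91 in KCl and 0.89 in log growth.

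With the Vip1D487A swaps turned, counts were 1 in log growth and 1 in KCl, ROK1 went from 2.23 to -0.39, LSM6 from -1.45 to 0.72, and the falling slope from -0.18 to -0.09. Without the 5 doubted arrays log counts were 81 in ipk1, 1512 in arg82, 1603 in vip1, 167 in kcs1, 1111 in snt1 and 85 in Vip1D487A. KCl counts were 1110 in vip1, 997 in kcs1, 972 in snt1 and 429 in Vip1D487A. The difference had 17 in ipk1, 397 in arg82, 742 in vip1, 6 in snt1, 17 in Vip1D487A and 707 in Rpd3ibs, the arrays labelled H2O2 523, rapamycin 664, and kcs1vip1 against vip1 1366. The falling Vip1D487A slope was -0.26.

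Leaving out 1 array gave ranges, and an array left alone took its spread from other groups. In log growth the counts were 32 to 1770 in ipk1, 64 to 168 in arg82, 62 to 309 in vip1, 9 to 31 in kcs1, 32 to 105 in snt1, 16 to 17 in Vip1D487A and 410 to 673 in Rpd3ibs. In KCl they were 946 to 1311 in arg82, 73 to 181 in vip1, 22 to 57 in kcs1, 15 to 70 in snt1, 16 to 144 in Vip1D487A and 903 to 923 in Rpd3ibs. For the difference they were 0 to 698 in ipk1, 27 to 128 in arg82, 7 to 165 in vip1, 0 to 43 in kcs1, 0 to 1 in snt1, 0 to 4 in Vip1D487A and 94 to 182 in Rpd3ibs. They were 1062 to 1797 in wild type H2O2, 20 to 301 on the arrays labelled H2O2, 360 to 826 for those minus log, 188 to 793 against kcs1 and 78 to 222 with rapamycin. The r of kcs1vip1 in log growth was 0.48 to 0.63 with arg82, 0.25 to 0.54 with kcs1 and 0.07 to 0.46 with Vip1D487A, and in KCl 0.07 to 0.64 with Vip1D487A. That of Rpd3ibs and rpd3 was 0.71 to 0.73 in log growth and 0.73 to 0.84 in KCl.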

Other observations

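The comparisons between arrays in this part were chosen after the results were seen.

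LEU2 was low in several strains and not in others. It fell in log growth in kcs1vip1 (-4.18 ± 0.20, n = 3), ipk1 (-4.80 ± 0.45) and snt1 (-4.67 ± 0.48, n = 2 each), less on the arrays labelled kcs1 (-1.70 ± 1.14), in arg82 (-1.63 ± 0.07) and in vip1 (-0.93 ± 0.18), and rose in Rpd3ibs (0.91 ± 0.53). LEU2 is also a marker gene, and LEU1 and OAC1, which are not, fell in log growth in kcs1vip1, ipk1, snt1 and arg82 and on the arrays labelled kcs1. URA3 rose in arg82 in log growth (1.28 ± 0.01) and in kcs1vip1 in KCl (1.07 ± 0.29), ADE2 in snt1 in log growth (1.32 ± 1.00), and CAN1 with rapamycin in kcs1vip1 in KCl (3.22 ± 0.48).

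The array without a group, both of whose channels are labelled kcs1vip1 in KCl, had STL1 at 14.37, CTT1 at 10.53, ALD3 at 10.04, DDR2 at 9.76 and GPD1 at 8.48, and NSR1 at -3.36, PHO12 at -3.32 and NOG1 at -3.21. Its osmotic median was 6.45, its ribosome biogenesis median -1.62 and its phosphate median -1.14. Across genes its r was 0.95, with a slope of 0.86, on the array of kcs1vip1 in KCl over kcs1vip1 in log growth, and 0.86, with a slope of 0.59, on the wild type KCl mean. ADE2 was 2.77 there and 2.52 on the direct kcs1vip1 array.

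The arrays of ipk1 replicate 2 in log growth and KCl, on the same slide, had an r of 0.85 with each other and phosphate medians of 1.82 and 2.38. Over all 34 replicate pairs r ran from 0.02 to 0.95 with a median of 0.745, and 25 pairs had at least 0.70. The predicted ratio of kcs1vip1 in KCl over log, built from the other groups, had r = 0.89 and slope 1.07 with the direct array, and that for H2O2 r = 0.54 and slope 0.22.

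Mitochondrially encoded genes shifted on some arrays, with chromosome medians, less that of the array, of -2.70 on the wild type rapamycin array and -1.17 and -1.58 on the snt1 log arrays. The largest shift of a nuclear chromosome was -0.38, of chromosome VI on ipk1 KCl replicate 2.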
